A study of Mus musculus with 56 samples.

How the data were processed

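Expression was measured on Affymetrix arrays, 51 of a first type (45101 probe sets) and 5 of a second (41345 transcript clusters), from tumour cells that were dissociated and purified on Percoll, or from sorted progenitors. The deposited values are log2 expression, for which the labels name RMA and Partek 6.5 with no order or role. Per the labels 28 arrays of the first type were made with a one cycle kit and 23 with an Affyexpress kit, and 3 tumours run with both kits were the basis of a batch correction. In the values, the mean difference between the kits over those 3 tumours was 0 within 5e-05 at each probe set, so the authors aligned the kits per probe set, and which arrays were moved is not shown. The standard error of that shift had a median of 0.1073 log2 and a 95th percentile of 0.2843 over probe sets. The tumours run with both kits correlated across probe sets at 0.996, 0.996 and 0.995. On the second type, each table was normalized apart and a correction across platforms is not stated for the values. For arrays there is no count depth, and signal over background limits dim genes.

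Probe sets were joined to genes by the reference annotation for each array type: 34958 of the first type had 1 gene, 932 had several and 9211 had none. For a gene with several probe sets (9012 of 18194 genes) the one with the highest mean over all arrays was used. The second type gave 22180 genes, of which 732 with identical values in all 4 carcinomas could not be tested and were left out, leaving 21448. Trp53 and members of the fixed lists that the join did not give were not analysed here.

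Groups, comparisons, 26 gene lists, tests and alternatives were fixed before the data were examined, from the sample labels, the design text and general knowledge of the cell types. Each gene was tested with limma 3.58.1 in R 4.3.3, in a fit of all 51 arrays with a term per group and for the kit. Arrays of the same tumour formed a random block (correlation 0.833), which left 40 residual degrees of freedom and a prior of 2.97. The 5 arrays of the second type were fitted apart (3 residual degrees of freedom, prior 1.23). There the lone medulloblastoma is assumed to vary like the carcinomas. A comparison weighs its groups equally. A gene passed, and is said to rise or fall, at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. Lists were tested against all other genes with limma's cameraPR at a preset correlation between genes of 0.01, adjusted over the 26 lists of a comparison, and another value used the correlation estimated for each list. Of the 82 list calls, 26 held with an estimated correlation. A list's median change, mean change and test had the same sign in each of the 82 calls. A list call is said to shift where fewer members passed than did not. Adjusted over the list alone means Benjamini-Hochberg over its members alone.

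Genes are named by a rule fixed in advance: the 10 largest rises and 10 largest falls among genes that passed, leaving out predicted genes and clones, up to 4 members of smallest adjusted p in each list and the member that moved most against it, and the genes the models were built on. The examples are drawn from these. Means and SDs of groups are over tumours, after averaging the arrays of a tumour. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 made the tables and figures.

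The fit was tested on simulated data, with 200 changed genes, a kit shift and the real layout. For in situ against SHH it recovered 92.5% of genes changed by 1 log2 and 47.8% of those changed by 0.5, with 4 unchanged genes called. Without the kit term 330 were. Recovery at 1 log2 was 74.6% for Blbp-Cre against Ptf1a-Cre, 68.7% for orthotopic against progenitors and 23.9% for the carcinomas. Genes were independent, so finding only the changed list tests no correlated list.

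Alternatives set in advance were no kit term, arrays of 1 kit, averaged arrays, only the groups compared, quantile normalization, the mean of a gene's probe sets, leaving out the dimmest 40% of genes, a trend with robust spread, the estimated correlation, and leaving out each array of groups of up to 5. The in situ tumours were also correlated with the models over 500 or all genes, by Spearman, after quantile normalization and with models from both kits. Chosen after seeing the data were leaving out in situ tumours with Ttr above 10, leaving out genes with tied carcinoma values, and lists without Mycn or with another of its probe sets. Each comparison of the first type was also repeated on other splits of its tumours, 100 or fewer.

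The labels conflict in places. The second-type repeat of Blbp-Cre tumour 1 has a title with Blbp and a genotype with Gad2, and was taken as Blbp-Cre. The design text lists the animal of Prom1-CreER tumour 4 under both Prom1 and Blbp, and its own label was used. Cdkn2c-/- orthotopic replicate 1 is outside the ranges of the design text and was kept in its labelled group.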

Results

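RNA was profiled on Affymetrix arrays in mouse models of medulloblastoma, a malignant tumour of the cerebellum and hindbrain, and of choroid plexus carcinoma, a tumour of the epithelium that makes cerebrospinal fluid. There were 56 arrays of 52 tumours or cell samples. Tumours called in situ here arose where they were started, after plasmids with Myc and dominant negative p53 flanked by loxP sites were electroporated into the fourth ventricle of embryos. They came from Blbp-Cre (5 tumours), Gad2-IRES-Cre (4) and Ptf1a-Cre (3) mice. Tumours called orthotopic here grew from Myc-infected granule neuron progenitors, the precursors of cerebellar granule neurons, implanted into the cortex of immunocompromised mice. Their donors were Cdkn2c-/-, Trp53-/- (6 tumours on 9 arrays), Atoh1-CreER, Trp53fl/- (4) or Prom1-CreER, Trp53fl/- (4) pups. Spontaneous tumours stood for the SHH class (8 from Nestin-Cre, Cdkn2c-/-, Trp53 floxed mice and 8 labelled Cdkn2c-/-, Ptch1+/-) and the WNT class (3, with stabilised beta-catenin). Sorted progenitors gave 3 samples. The second array type held 4 carcinomas and a repeat of Blbp-Cre tumour 1. Array medians ran from 5.32 to 5.49 log2 on the first type and from 6.6 to 6.7 on the second, and the number of arrays limits the precision. Below, a value after ± is the standard error of a log2 difference unless SD is written.

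The genes that the models were built on were read first, in every sample. Myc, a transcription factor that drives growth, had group means from 8.08 ± 0.43 (SD, n = 3) in Ptf1a-Cre tumours to 9.17 ± 0.78 (SD, n = 4) in Prom1-CreER tumours. Without introduced Myc its means ran from 4.82 ± 0.12 (SD, n = 3) in progenitors to 5.70 ± 0.60 (SD, n = 8) in Nestin-Cre SHH tumours, and the lowest Myc tumour (7.35) lay above the highest of these samples (6.48). Cdkn2c, a cell cycle inhibitor, was at 5.81 ± 0.25 (SD, n = 8) in Nestin-Cre SHH, 6.03 ± 0.42 (SD, n = 6) in Cdkn2c-/- orthotopic tumours and 5.49 ± 0.29 (SD, n = 3) in progenitors, against 9.52 ± 0.61 (SD, n = 3) in WNT tumours, but groups not labelled Cdkn2c-/- were also low, such as Atoh1-CreER (6.51 ± 0.44, SD, n = 4) and Blbp-Cre tumours (6.59 ± 0.54, SD, n = 5). Of the 8 Ptch1+/- SHH tumours, replicates 2 and 3 were at 9.13 and 9.10, and the lowest was at 5.40. Whether the probe set lies in the deleted part of the gene is not given, so this reading does not test the label. Ptch1, the receptor that holds SHH signalling off, was at 12.01 and 12.04 in Nestin-Cre SHH replicates 4 and 6 and as low as 3.71 in the other 6. In the Ptch1+/- SHH tumours it was at 10.09 to 12.59. Ctnnb1, whose product is beta-catenin, had means from 12.02 ± 0.20 (SD, n = 4) to 12.68 ± 0.07 (SD, n = 3). Trp53 was not analysed here.

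Genes whose promoters drive the Cre lines were read likewise. Atoh1, the transcription factor of granule neuron progenitors, was at 10.58 ± 0.91 (SD, n = 8) in Nestin-Cre SHH, 9.97 ± 1.03 (SD, n = 8) in Ptch1+/- SHH and 9.53 ± 0.22 (SD, n = 3) in progenitors. Its means in the other groups lay between 4.10 ± 0.15 (SD, n = 3) in WNT and 5.20 ± 1.68 (SD, n = 4) in Gad2-IRES-Cre tumours, and in Atoh1-CreER tumours it was 4.35 ± 0.67 (SD, n = 4). Gad2, an enzyme of GABA synthesis, was between 3.29 ± 0.19 (SD, n = 3) and 3.77 ± 0.30 (SD, n = 3), and at 3.40 ± 0.16 (SD, n = 4) in Gad2-IRES-Cre tumours. Ptf1a, a transcription factor of GABAergic progenitors, was highest in progenitors at 5.64 ± 0.74 (SD, n = 3) and at 3.87 ± 1.04 (SD, n = 3) in Ptf1a-Cre tumours. Fabp7, which encodes Blbp, was at 9.59 ± 1.13 (SD, n = 5) in Blbp-Cre, 9.73 ± 0.70 (SD, n = 4) in Gad2-IRES-Cre and 6.44 ± 2.07 (SD, n = 6) in Cdkn2c-/- orthotopic tumours. Prom1 means ran from 8.47 ± 0.99 (SD, n = 3) to 10.29 ± 0.28 (SD, n = 6). Nes (nestin) means ran from 6.25 ± 0.08 (SD, n = 3) to 7.78 ± 0.52 (SD, n = 3).

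**Figure D1:**
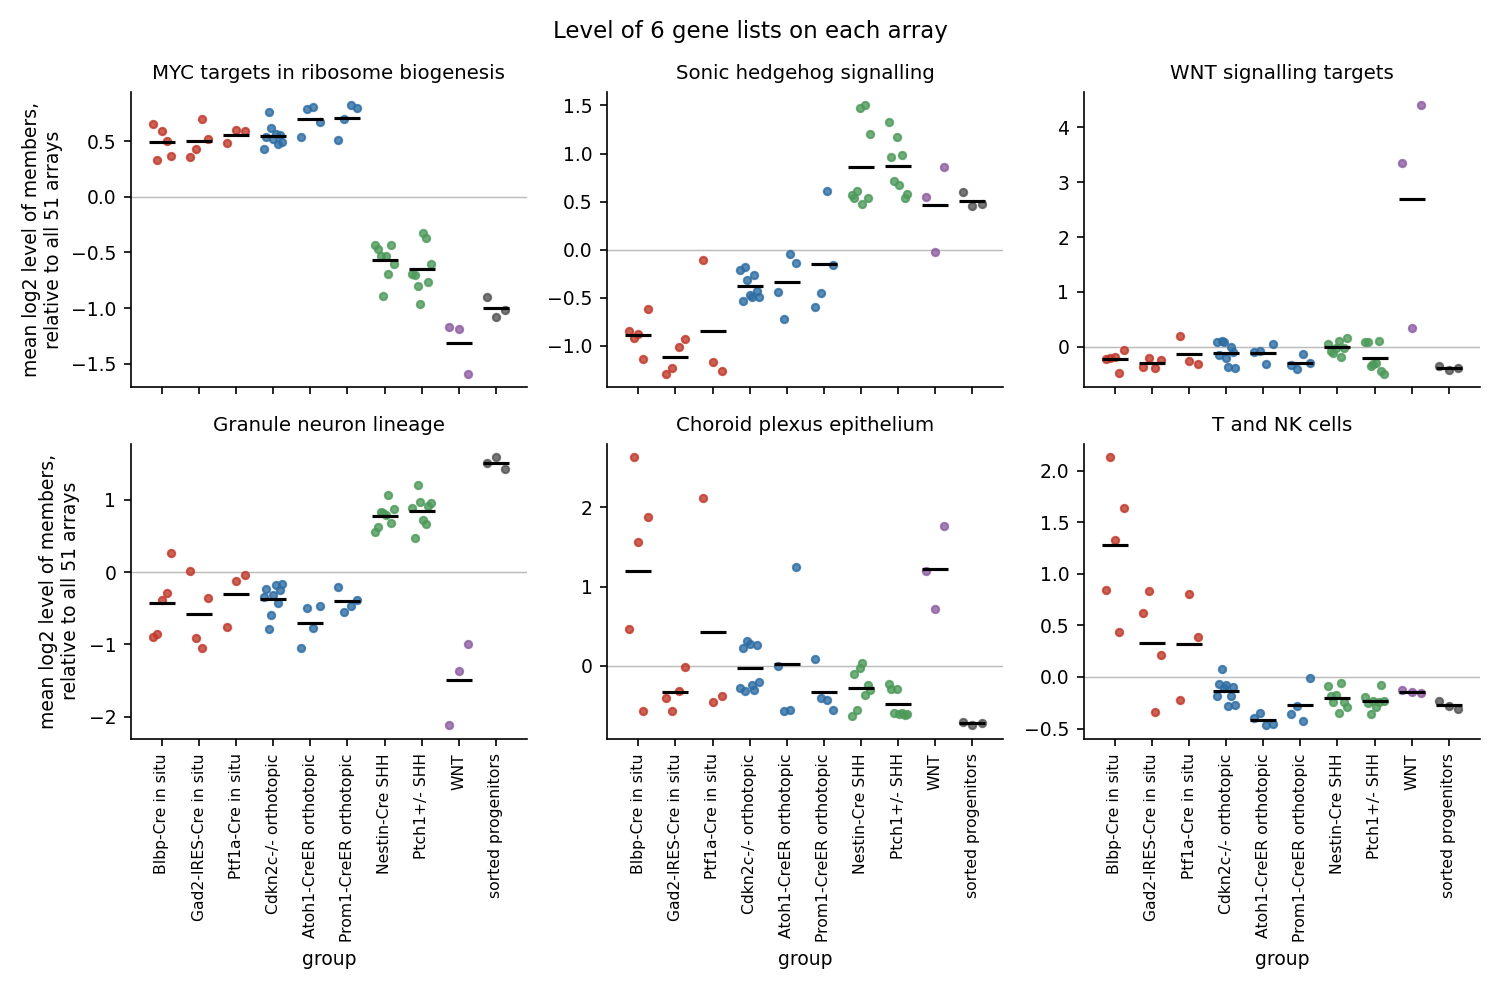
Mean log2 level of the members of 6 fixed gene lists on each of the 51 arrays of the first type, relative to the mean of all 51, by group; each point is an array and each line a group mean. Ribosome biogenesis targets of MYC lie above 0 in the in situ and orthotopic groups and below 0 in the others, and T and NK cell genes reach 2.13 in Blbp-Cre tumour 2.

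The study's first question set the in situ tumours against its earlier models, beginning with SHH medulloblastoma (12 against 16 tumours). Genes of ribosome production were higher in situ and genes of the granule neuron lineage and of SHH signalling were lower. Hsd11b2, which inactivates corticosterone, fell by 5.88 ± 0.29 log2 and Gsg1l, a partner of AMPA receptors, fell by 5.90 ± 0.33, both below every SHH tumour in 12 of 12 in situ tumours. Also lower were the granule neuron transcription factors Atoh1 (-5.19 ± 0.42) and Barhl1 (-5.17 ± 0.21), the neurotrophin receptor Ntrk3 (-5.03 ± 0.34) and the netrin receptor Dcc (-5.68 ± 0.62). On the higher side stood Ptger3, a prostaglandin E receptor (5.77 ± 0.50, adjusted p = 1.1e-12), Nefh, the heavy neurofilament chain (5.62 ± 0.38, adjusted p = 6.5e-16), and Tuba4a, an alpha tubulin (5.25 ± 0.28, adjusted p = 6.9e-19), each above every SHH tumour in 12 of 12 tumours. Immune transcripts rose unevenly: Cxcl9, a chemokine induced by interferon gamma, by 5.39 ± 0.68 and Jchain, which joins IgM and IgA units, by 4.97 ± 0.89, above every SHH tumour in 10 of 12 and 9 of 12 in situ tumours.

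By fixed list, among MYC targets in ribosome biogenesis 28 of 30 measured members rose, 0 fell and 2 did not pass (28 and 0 adjusted over the list alone), with adjusted p = 4.6e-22, and adjusted p = 0.00166 with an estimated correlation. Bop1 and Pes1, partners in maturing the large ribosomal subunit, rose by 2.26 ± 0.14 and 1.38 ± 0.10. Metabolic MYC targets also rose (18 rose, 0 fell and 6 did not pass of 24 measured, 18 and 0 adjusted over the list alone), with adjusted p = 2.2e-12, and adjusted p = 0.00166 with an estimated correlation, among them Srm, spermidine synthase (2.53 ± 0.15), and Ldha, lactate dehydrogenase (2.06 ± 0.18). In the SHH list, 1 of 14 measured members rose, 9 fell and 4 did not pass (2 and 9 adjusted over the list alone), with adjusted p = 1.6e-08, and adjusted p = 0.00166 with an estimated correlation. Lower were Gli1 (-4.97 ± 0.32), Boc (-4.16 ± 0.30) and Sfrp1 (-5.20 ± 0.28), and Ptch1 was at 1.58 (adjusted p = 0.0811, but 0.015 with no kit term, 0.0189 with averaged arrays and 0.0346 without dim genes). Mycn, a member, had group means of 5.07 to 5.24 in situ and 11.27 and 11.73 in SHH at a probe set not used. For the granule neuron lineage 2 of 23 measured members rose, 14 fell and 7 did not pass (3 and 16 adjusted over the list alone), with adjusted p = 1.2e-08, and adjusted p = 0.00403 with an estimated correlation. Zic1 (-1.42 ± 0.13) and Meis1 (-1.86 ± 0.20) fell, while Gabra6, a GABA receptor subunit of mature granule neurons, rose by 2.51 ± 0.70. Hypoxia and glycolysis genes rose (17 rose, 0 fell and 4 did not pass of 21 measured, 17 and 0 adjusted over the list alone), with adjusted p = 7.1e-10, and adjusted p = 0.0195 with an estimated correlation, led by the lactate exporter Slc16a3 (3.33 ± 0.25) and by Pdk1 (3.23 ± 0.24).

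Markers of other cell types moved with this comparison. Microglia and macrophage genes rose, such as Aif1 (3.20 ± 0.42) and Cd68 (2.87 ± 0.41). Of 22 measured members 21 rose, 0 fell and 1 did not pass (21 and 0 adjusted over the list alone), adjusted p = 2.9e-08, and adjusted p = 0.517 with an estimated correlation. T and NK cell genes rose, such as granzyme A, Gzma (1.90 ± 0.28), and Ccl5 (3.21 ± 0.49). Among its 19 measured members 13 rose, 1 fell and 5 did not pass (14 and 1 adjusted over the list alone), adjusted p = 0.00821, and adjusted p = 0.766 with an estimated correlation. Among interferon and antigen presentation genes, with the MHC class II genes H2-Ab1 (3.88 ± 0.52) and Cd74 (2.68 ± 0.43), 17 of 24 measured members rose, 0 fell and 7 did not pass (17 and 0 adjusted over the list alone), adjusted p = 0.00201, and adjusted p = 0.766 with an estimated correlation. Fibroblast and mural genes rose, Mgp by 3.11 ± 0.53, though Pdgfra fell by 3.22 ± 0.50. In all 15 of 19 measured members rose, 1 fell and 3 did not pass (15 and 1 adjusted over the list alone), adjusted p = 0.0307, and adjusted p = 0.766 with an estimated correlation. For choroid plexus epithelium, with Car12 (5.14 ± 0.24), Igfbp2 (5.26 ± 0.44), Krt8 (2.48 ± 0.63) and Otx2 (-3.67 ± 1.00), 11 of 28 measured members rose, 3 fell and 14 did not pass (14 and 3 adjusted over the list alone), adjusted p = 0.0435, and adjusted p = 0.766 with an estimated correlation. In all, 8003 of 18194 genes passed (4832 higher and 3171 lower), and after quantile normalization 3882 were higher and 4307 lower. The choroid plexus call ended without Blbp-Cre tumour 2, 3 or 5 , Gad2-IRES-Cre tumour 3 or 4 or Ptf1a-Cre tumour 1 (adjusted p from 0.0504 to 0.232), and the fibroblast call without Gad2-IRES-Cre tumour 4 (adjusted p = 0.0580). Leaving out dim genes ended the choroid plexus (adjusted p = 0.255), T and NK cell (adjusted p = 0.587) and fibroblast calls (adjusted p = 0.214), as leaving out the 5 in situ tumours with Ttr above 10 did for fibroblasts (adjusted p = 0.0602), which leaves 1 Blbp-Cre tumour.

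Set against WNT medulloblastoma (12 against 3 tumours), the in situ tumours were higher in the MYC target lists and, at the preset correlation alone, lower in the list of WNT targets. Among the largest rises, Nhlh2, Nhlh1 and Insm1, transcription factors of immature neurons, rose by 5.77 ± 0.35, 4.87 ± 0.44 and 4.99 ± 0.45, above every WNT tumour in 12 of 12 tumours, and Stmn2, a protein of growing axons, by 5.58 ± 0.64. Lower were the feedback inhibitors of WNT signalling Wif1 (-6.92 ± 1.03) and Nkd1 (-5.33 ± 0.67) and the matrix proteoglycan Vcan (-5.03 ± 0.64). Of 18194 genes 7753 passed, 4112 higher and 3641 lower. In the WNT target list 1 of 19 measured members rose, 16 fell and 2 did not pass (1 and 17 adjusted over the list alone), adjusted p = 1.8e-08, and adjusted p = 0.0978 with an estimated correlation, with Bmp4 (-5.22 ± 0.46) and Apcdd1 (-4.56 ± 0.53) lower and the stem cell receptor Lgr5 (1.85 ± 0.39) higher. WNT tumour 2 was low at these targets, with Nkd1 at 6.65 against 12.38 and 12.83, and without it Nkd1 was at -7.31, Wif1 at -8.52 and the list at adjusted p = 1.04e-25.

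MYC targets of ribosome biogenesis rose against WNT as well, Nop56 by 3.08 ± 0.15 and Ncl by 1.79 ± 0.09. There 29 of 30 measured members rose, 0 fell and 1 did not pass (29 and 0 adjusted over the list alone), adjusted p = 2.5e-34, and adjusted p = 2.5e-05 with an estimated correlation. Metabolic targets of MYC followed, with the chaperonins Hspd1 (2.16 ± 0.13) and Hspe1 (2.18 ± 0.14). Over 24 measured members 23 rose, 0 fell and 1 did not pass (24 and 0 adjusted over the list alone), adjusted p = 3.6e-21, and adjusted p = 5.8e-06 with an estimated correlation. Cell cycle genes rose, such as the replication helicase subunit Mcm6 (2.02 ± 0.15) and Birc5 (1.99 ± 0.16). Of 29 measured members 27 rose, 0 fell and 2 did not pass (28 and 0 adjusted over the list alone), adjusted p = 2.6e-17, and adjusted p = 0.018 with an estimated correlation. Granule neuron genes rose more often than they fell, with Zic1 higher by 1.72 ± 0.18 and Meis2 lower by 2.60 ± 0.73. Among its 23 measured members 9 rose, 3 fell and 11 did not pass (9 and 3 adjusted over the list alone), adjusted p = 0.0108, and adjusted p = 0.39 with an estimated correlation. SHH genes fell, among them Eya1 (-4.90 ± 0.72) and Cdon (-2.96 ± 0.55). In all 1 of 14 measured members rose, 7 fell and 6 did not pass (1 and 8 adjusted over the list alone), adjusted p = 0.0121, and adjusted p = 0.372 with an estimated correlation. Radial glia genes fell, such as Hes1 (-2.86 ± 0.31) and Notch1 (-2.91 ± 0.49), while the RNA-binding protein gene Msi1 rose by 2.50 ± 0.31. There 1 of 22 measured members rose, 11 fell and 10 did not pass (1 and 11 adjusted over the list alone), adjusted p = 0.0108, and adjusted p = 0.427 with an estimated correlation. Glycolysis genes shifted up as a list, with Pkm (2.27 ± 0.23) and Hk2 (2.47 ± 0.30). Over 21 measured members 10 rose, 0 fell and 11 did not pass (10 and 0 adjusted over the list alone), adjusted p = 0.00603, and adjusted p = 0.5 with an estimated correlation. Microglia genes rose, with lysozyme Lyz2 at 3.57 ± 0.69 and Spi1 at 0.89 ± 0.18. Of 22 measured members 16 rose, 0 fell and 6 did not pass (17 and 0 adjusted over the list alone), adjusted p = 0.00526, and adjusted p = 0.804 with an estimated correlation. Without WNT tumour 1 the granule neuron (adjusted p = 0.0638) and microglia calls (adjusted p = 0.341) ended, and without dim genes the glycolysis (adjusted p = 0.134) and microglia calls (adjusted p = 0.0659).

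Against the orthotopic Myc tumours (12 against 14 tumours), which carry the same oncogene but grew in another place and host, the in situ tumours were higher in the T and NK cell list. Among the largest rises, Jchain rose by 6.16 ± 0.72, the immunoglobulin genes Igha and Ighm by 4.64 ± 0.58 and 4.14 ± 0.61, and the chemokine genes Cxcl9 and Ccl8 by 5.00 ± 0.55 and 3.55 ± 0.39. Crabp1, a retinoic acid binding protein of the embryonic nervous system, rose by 3.59 ± 0.52. Lower were the immediate early genes Fos (-2.52 ± 0.63, below every orthotopic tumour in 0 of 12) and Egr1 (-1.90 ± 0.47), the hindbrain transcription factor Olig3 (-2.21 ± 0.54) and Sox1 (-1.93 ± 0.41). At the brightest of its 3 probe sets Mycn was at -7.46 ± 0.11, adjusted p = 1.2e-41, from 13.42 ± 0.30 (SD, n = 6), 13.67 ± 0.22 (SD, n = 4) and 13.74 ± 0.41 (SD, n = 4) in the orthotopic groups. Another Mycn probe set read 5.62 ± 0.89 (SD, n = 6), 5.17 ± 0.79 (SD, n = 4) and 6.54 ± 0.89 (SD, n = 4) there, and 5.24 ± 1.14 (SD, n = 5) in Blbp-Cre tumours, so the probe sets disagree.

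By list, T and NK cell genes rose in situ, such as Cd3d (1.47 ± 0.19), Ccl5 (3.08 ± 0.40) and Gzmb (1.76 ± 0.25). Among its 19 measured members 14 rose, 0 fell and 5 did not pass (16 and 0 adjusted over the list alone), adjusted p = 2.8e-20, and adjusted p = 0.00267 with an estimated correlation. Interferon and antigen presentation genes rose, Gbp2 by 3.82 ± 0.54 and H2-Aa by 3.41 ± 0.53. In all 16 of 24 measured members rose, 0 fell and 8 did not pass (19 and 0 adjusted over the list alone), adjusted p = 9.1e-20, and adjusted p = 0.0755 with an estimated correlation. Microglia and macrophage genes rose, Aif1 by 2.08 ± 0.34 and the leukocyte phosphatase Ptprc by 2.09 ± 0.41. There 15 of 22 measured members rose, 0 fell and 7 did not pass (17 and 0 adjusted over the list alone), adjusted p = 2.2e-11, and adjusted p = 0.319 with an estimated correlation. Astrocyte genes shifted up as a list, with Aldoc at 2.44 ± 0.49 and the water channel Aqp4 at 2.37 ± 0.64. Over 14 measured members 6 rose, 0 fell and 8 did not pass (10 and 0 adjusted over the list alone), adjusted p = 4.1e-05, and adjusted p = 0.331 with an estimated correlation. GABAergic genes shifted up, with the GABA-synthesising enzyme Gad1 at 3.30 ± 0.43 and Calb1 at 3.12 ± 0.55. Of 21 measured members 5 rose, 0 fell and 16 did not pass (5 and 0 adjusted over the list alone), adjusted p = 0.0036, and adjusted p = 0.0755 with an estimated correlation. Mature neuron genes shifted up, with the glutamate transporter Slc17a6 (1.92 ± 0.45) and Syt1 (1.19 ± 0.32). Among its 17 measured members 5 rose, 0 fell and 12 did not pass (5 and 0 adjusted over the list alone), adjusted p = 0.0365, and adjusted p = 0.453 with an estimated correlation. Choroid plexus genes shifted up, with Krt8 (1.65 ± 0.51) and Slc13a4 (0.78 ± 0.26) passing. Krt8 did not pass without Ptf1a-Cre tumour 3 (adjusted p = 0.127) or any of 6 other tumours, nor Slc13a4 without Ptf1a-Cre tumour 1 (0.48, adjusted p = 0.234) or any of 12 others. In all 2 of 28 measured members rose, 0 fell and 26 did not pass (11 and 2 adjusted over the list alone), adjusted p = 0.00527, and adjusted p = 0.525 with an estimated correlation. Endothelial genes shifted down, with Robo4 (-0.71 ± 0.15) and Erg (-0.47 ± 0.12). There 0 of 18 measured members rose, 4 fell and 14 did not pass (0 and 6 adjusted over the list alone), adjusted p = 4.1e-05, and adjusted p = 0.475 with an estimated correlation.

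Fibroblast and mural genes also shifted down in situ as a list, with Pdgfrb (-1.87 ± 0.33) and Col1a1 (-1.25 ± 0.26) lower, while Thy1 rose by 1.25 ± 0.26. Over 19 measured members 1 rose, 4 fell and 14 did not pass (1 and 7 adjusted over the list alone), adjusted p = 0.00455, and adjusted p = 0.508 with an estimated correlation. MYC targets of ribosome biogenesis shifted down, with Polr1b (-0.71 ± 0.14) and Dkc1 (-0.41 ± 0.10) lower. Of 30 measured members 1 rose, 3 fell and 26 did not pass (1 and 8 adjusted over the list alone), adjusted p = 9.6e-04, and adjusted p = 0.475 with an estimated correlation. The SHH list shifted down, with Gas1 at -0.97 ± 0.24 beside Mycn. Among its 14 measured members 1 rose, 3 fell and 10 did not pass (1 and 4 adjusted over the list alone), adjusted p = 5.0e-24, and adjusted p = 1.4e-09 with an estimated correlation. Without Mycn that call ended (adjusted p = 0.434), as it did with another Mycn probe set (adjusted p = 0.255). Of 18194 genes 1858 passed, 1162 higher and 696 lower, and after quantile normalization 909 were higher and 963 lower. Without dim genes 1200 genes passed. The choroid plexus, mature neuron and GABAergic calls ended (adjusted p = 0.685, 0.112 and 0.685), the last reversed. Without the 5 tumours with Ttr above 10, 825 passed, the astrocyte call ended and the choroid plexus list reversed (adjusted p = 0.0980 and 0.0352). There Aldoc was at 1.35 (adjusted p = 0.217) and Aqp4 at 2.40 (adjusted p = 0.0925), and Slc13a4 (0.05), Syt1 (0.77), Thy1 (0.78), Col1a1 (-0.78), Polr1b (-0.42) and Pdgfrb (-1.33) were smaller and did not pass, nor did Fos (-2.63), Krt8 (1.61), Robo4 (-0.62), Erg (-0.52) and Dkc1 (-0.38), which changed less (adjusted p from 0.0531 to 0.958). With arrays of the same kit alone the mature neuron call ended (adjusted p = 0.241) and Aqp4, Slc17a6, Syt1, Krt8, Slc13a4, Erg and Gas1 did not pass (adjusted p = 0.105, 0.0671, 0.0940, 0.193, 0.198, 0.0737 and 0.0705), and in a fit of only these groups the mature neuron call (adjusted p = 0.0696), Krt8 (adjusted p = 0.126) and Slc13a4 (adjusted p = 0.139). With the mean of its probe sets Syt1 was at 0.40 (adjusted p = 0.150). The mature neuron call also ended without Atoh1-CreER tumour 3 , Gad2-IRES-Cre tumour 1, Prom1-CreER tumour 4 or Ptf1a-Cre tumour 2 or 3 (adjusted p from 0.0529 to 0.0791), and the choroid plexus call without Ptf1a-Cre tumour 1 (adjusted p = 0.285).

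To place each in situ tumour among the earlier models, its profile was correlated across the 1000 genes of highest variance between the model means, each centred on the mean of the 4 models. All 12 in situ tumours were closest to the Cdkn2c-/- orthotopic Myc model. The mean Pearson r was 0.638 ± 0.084 (SD, n = 12) with that model, 0.014 ± 0.153 (SD, n = 12) with WNT, -0.313 ± 0.054 (SD, n = 12) with SHH and -0.386 ± 0.106 (SD, n = 12) with progenitors. The lowest r with the Myc model was 0.467, in Blbp-Cre tumour 5, which was also the tumour closest to WNT (r = 0.244). Genes are not independent replicates.

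**Figure D2:**
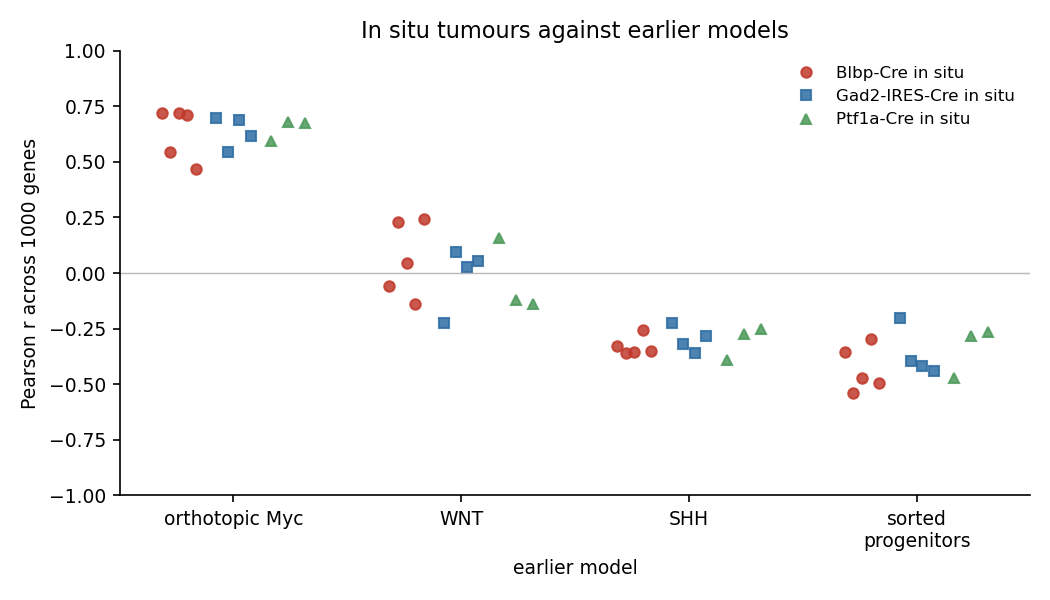
Pearson correlation across genes of each of the 12 in situ tumours with the mean profile of 4 earlier models, by Cre line; each point is a tumour. Each tumour has its highest value, between 0.467 and 0.721, with the orthotopic Myc model.

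The 3 Cre lines were compared to ask whether the cell in which the plasmids recombine leaves a mark on the tumour. Blbp-Cre tumours were higher than Gad2-IRES-Cre tumours in the choroid plexus and T and NK cell lists. Kcne2, a potassium channel subunit of choroid plexus, rose by 4.04 ± 0.88 (SD 3.37 against 0.25). Frem1, a basement membrane protein, rose by 3.54 ± 0.71 and Ms4a4b, a T cell protein, by 3.05 ± 0.45. Lower in Blbp-Cre tumours were Ffar4, a fatty acid receptor (-2.43 ± 0.24, adjusted p = 1.5e-08, below every Gad2-IRES-Cre tumour in 5 of 5 tumours) and Vps52 (-1.35 ± 0.22). Choroid plexus genes shifted up as a list, with Cldn1 at 2.57 ± 0.69. In all 3 of 28 measured members rose, 0 fell and 25 did not pass (16 and 0 adjusted over the list alone), adjusted p = 3.1e-15, and adjusted p = 0.0379 with an estimated correlation. T and NK cell genes shifted up, with Cd3g at 2.03 ± 0.38. There 7 of 19 measured members rose, 0 fell and 12 did not pass (15 and 0 adjusted over the list alone), adjusted p = 1.8e-22, and adjusted p = 0.00213 with an estimated correlation. Interferon genes shifted up, with the peptide transporter Tap2 at 1.60 ± 0.38. Over 24 measured members 2 rose, 0 fell and 22 did not pass (14 and 0 adjusted over the list alone), adjusted p = 1.0e-16, and adjusted p = 0.174 with an estimated correlation. For microglia and macrophages, with Ptprc at 1.29, 0 of 22 measured members rose, 0 fell and 22 did not pass (0 and 0 adjusted over the list alone), adjusted p = 4.2e-04, and adjusted p = 0.74 with an estimated correlation.

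The gene count between these lines was 217 of 18194 (137 higher and 80 lower in Blbp-Cre), and it depended on single tumours. Without Blbp-Cre tumour 1, 2, 3, 4 or 5 it was 340, 94, 118, 406 and 109, and without Gad2-IRES-Cre tumour 3 it was 51, where the microglia call ended too (adjusted p = 0.0728). Cldn1 did not pass without Blbp-Cre tumour 2, 3 or 5 or Gad2-IRES-Cre tumour 1, 2 or 3, nor Tap2 without Blbp-Cre tumour 2, 3 or 5 or Gad2-IRES-Cre tumour 3, nor Kcne2 without Blbp-Cre tumour 2 or 5 (adjusted p from 0.0596 to 0.213). With the mean of their probe sets Cldn1 was at 0.88 (adjusted p = 0.0513) and Vps52 at -0.65 (adjusted p = 0.143). With arrays of the same kit alone 48 genes passed, without Cd3g, Cldn1, Kcne2, Ms4a4b and Tap2 (adjusted p = 0.141, 0.222, 0.205, 0.0560 and 0.135), whose changes stayed at 2.03, 2.57, 4.03, 3.05 and 1.60 while the error changed. Without dim genes 84 passed, and in a limma fit of only these lines 0 passed and 1458 had an unadjusted p under 0.05. Leaving out the 5 tumours with Ttr above 10 leaves Blbp-Cre tumour 4 alone in that line, which tests neither the line nor these calls.

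Between Blbp-Cre and Ptf1a-Cre tumours 138 of 18194 genes passed, 75 higher and 63 lower in Blbp-Cre. Tnfsf10, the death receptor ligand TRAIL, rose by 2.55 ± 0.49. Lower were the tight junction gene Cldn6 (-2.72 ± 0.50) and Sycp2l, a meiosis gene (-4.06 ± 0.56), which was at 2.99 to 3.12 in Blbp-Cre tumours but also low, at 3.20, in 1 of the Ptf1a-Cre tumours (highest 9.22). T and NK cell genes shifted up as a list, with Gzma at 1.94 ± 0.40 (adjusted p = 0.106 without Ptf1a-Cre tumour 1). Of 19 measured members 5 rose, 0 fell and 14 did not pass (12 and 0 adjusted over the list alone), adjusted p = 5.2e-18, and adjusted p = 0.0111 with an estimated correlation. Interferon and antigen presentation genes shifted up as a list, with Cd74 at 2.01. Among its 24 measured members 0 rose, 0 fell and 24 did not pass (7 and 0 adjusted over the list alone), adjusted p = 1.7e-12, and adjusted p = 0.588 with an estimated correlation. Microglia genes did likewise, with Aif1 at 1.81. In all 0 of 22 measured members rose, 0 fell and 22 did not pass (0 and 0 adjusted over the list alone), adjusted p = 1.0e-06, and adjusted p = 0.84 with an estimated correlation. Choroid plexus genes, with Kcne2 at 2.53, shifted up. There 0 of 28 measured members rose, 0 fell and 28 did not pass (0 and 0 adjusted over the list alone), adjusted p = 8.1e-04, and adjusted p = 0.84 with an estimated correlation. Hindbrain genes, with Hoxa3 at 0.81, shifted up. Over 16 measured members 0 rose, 0 fell and 16 did not pass (1 and 0 adjusted over the list alone), adjusted p = 0.045, and adjusted p = 0.809 with an estimated correlation. Cell cycle genes, with Tyms at -0.81, shifted down. Of 29 measured members 0 rose, 0 fell and 29 did not pass (0 and 0 adjusted over the list alone), adjusted p = 0.045, and adjusted p = 0.89 with an estimated correlation.

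Single tumours moved this count as well: without Blbp-Cre tumour 1, 2, 3, 4 or 5 it was 244, 87, 85, 227 and 72, and without Ptf1a-Cre tumour 3 it was 70. With arrays of the same kit 0 genes passed and 2054 had an unadjusted p under 0.05 in limma, in a fit of only these lines 8 passed, none of them named here, and without dim genes 32. The cell cycle call ended without Blbp-Cre tumour 2 or 5 or Ptf1a-Cre tumour 2 or 3 (adjusted p from 0.152 to 0.422), and the hindbrain call without Blbp-Cre tumour 1 or 4 or Ptf1a-Cre tumour 2 or 3 (adjusted p from 0.129 to 0.535). The choroid plexus call ended without Blbp-Cre tumour 2 or Ptf1a-Cre tumour 2 or 3 (adjusted p from 0.137 to 0.535), and the microglia call without Ptf1a-Cre tumour 1 (adjusted p = 0.0820). The hindbrain call also ended with averaged arrays, arrays of the same kit, only these lines, quantile normalization and no dim genes (adjusted p from 0.0536 to 0.294). So did the cell cycle call with averaged arrays, quantile normalization and no dim genes (adjusted p from 0.0542 to 0.197), the choroid plexus call with only these lines and no dim genes (adjusted p = 0.0681 and 0.0766), and the T and NK cell call with no dim genes (adjusted p = 0.0766). Some members passed when a tumour was left out: Kcne2 without Ptf1a-Cre tumour 1 (4.09, adjusted p = 0.0404) or Blbp-Cre tumour 4 (3.60, adjusted p = 0.0148), Cd74 without the latter (2.50, adjusted p = 0.0233), and Hoxa3 without Ptf1a-Cre tumour 1 (1.13, adjusted p = 0.0405) or Blbp-Cre tumour 5 (1.08, adjusted p = 0.0161).

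Between Gad2-IRES-Cre and Ptf1a-Cre tumours 32 of 18194 genes passed, 7 higher and 25 lower in Gad2-IRES-Cre. Ffar4 rose by 2.02 ± 0.28 and Cnnm1 by 1.94 ± 0.36, while Sycp2l (-4.12 ± 0.59, SD 0.11 against 3.41) and Cldn6 (-2.34 ± 0.52) fell. Cldn6 did not pass without Gad2-IRES-Cre tumour 2, 3 or 4 or Ptf1a-Cre tumour 2 or 3 (adjusted p from 0.0907 to 0.265), and with the mean of its probe sets Cnnm1 was at 0.91 (adjusted p = 0.0561). Choroid plexus genes shifted down as a list, with Krt8 at -3.04, which passed without Ptf1a-Cre tumour 1 (-4.47, adjusted p = 0.0310) or Gad2-IRES-Cre tumour 1 (-4.30, adjusted p = 0.0116). Among its 28 measured members 0 rose, 0 fell and 28 did not pass (0 and 0 adjusted over the list alone), adjusted p = 6.5e-04, and adjusted p = 0.955 with an estimated correlation. Without Ptf1a-Cre tumour 1 (adjusted p = 0.719) that list turned direction, and without dim genes the call ended (adjusted p = 0.568). Leaving out single tumours the count ran from 16 to 70, with arrays of the same kit it was 1, without dim genes 14, and in a limma fit of only these lines 0, with 907 genes at an unadjusted p under 0.05.

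Ttr, the transport protein transthyretin and the most abundant transcript of choroid plexus, set tumours apart within the Cre lines. It was at 12.45, 14.11, 13.62 and 14.13 in Blbp-Cre tumours 1, 2, 3 and 5 and at 14.07 in Ptf1a-Cre tumour 1. Blbp-Cre tumour 4 was at 4.52, Gad2-IRES-Cre tumours between 4.49 and 7.40, and Ptf1a-Cre tumours 2 and 3 at 4.39 and 4.09. T cell transcripts stood out in part of the same tumours, with Cd3g at 8.01, 6.42 and 6.85 in Blbp-Cre tumours 2, 3 and 5 and at 3.13 in Ptf1a-Cre tumour 1.

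**Figure D3:**
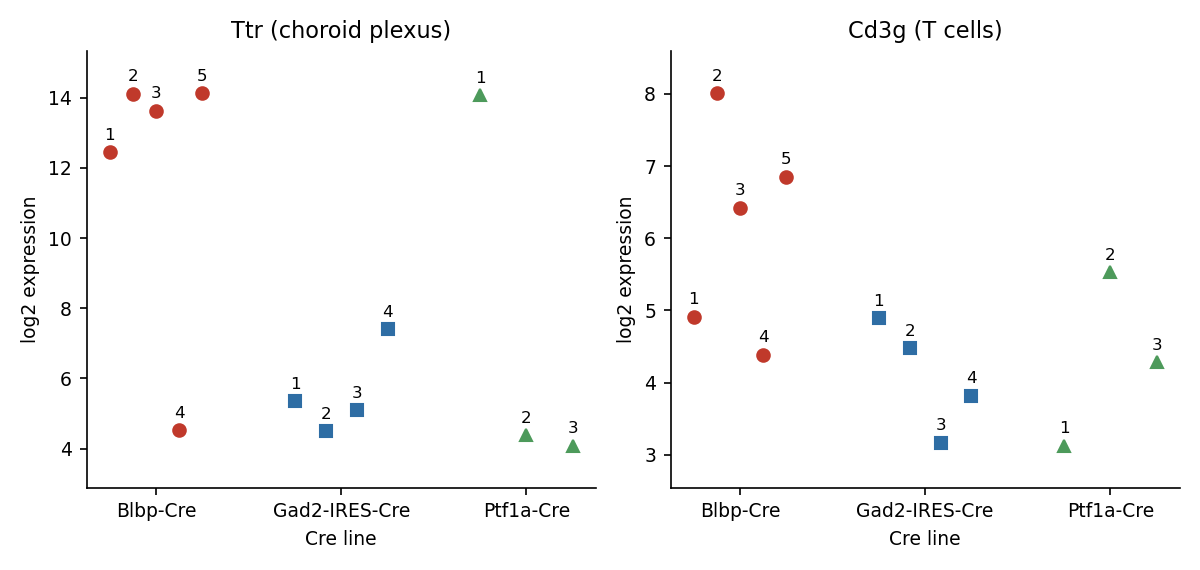
Log2 level of Ttr, a choroid plexus transcript, and of Cd3g, a T cell transcript, in each of the 12 in situ tumours by Cre line; each point is a tumour, with its replicate number. Ttr is above 10 in 4 Blbp-Cre tumours and 1 Ptf1a-Cre tumour.

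Orthotopic tumours from Atoh1-CreER and Prom1-CreER donors (4 against 4) ask whether the cells marked by either line give different tumours. By limma 0 of 18194 genes passed and 725 had an unadjusted p under 0.05. Astrocyte genes shifted up in Atoh1-CreER tumours as a list, with the metabolic enzyme genes Aldh1l1 at 1.33 and Aldoc at 1.27. In all 0 of 14 measured members rose, 0 fell and 14 did not pass (0 and 0 adjusted over the list alone), adjusted p = 1.6e-07, and adjusted p = 0.194 with an estimated correlation. Radial glia genes shifted up, with Fabp7 at 1.58 and Bcan at 0.97. There 0 of 22 measured members rose, 0 fell and 22 did not pass (0 and 0 adjusted over the list alone), adjusted p = 2.0e-04, and adjusted p = 0.194 with an estimated correlation. Microglia genes shifted up, with Aif1 at 0.65. Over 22 measured members 0 rose, 0 fell and 22 did not pass (0 and 0 adjusted over the list alone), adjusted p = 0.0268, and adjusted p = 0.99 with an estimated correlation. GABAergic genes shifted down, with Dlx2 at -0.17 and Neurog2 against the list at 0.40. Of 21 measured members 0 rose, 0 fell and 21 did not pass (0 and 0 adjusted over the list alone), adjusted p = 0.0268, and adjusted p = 0.194 with an estimated correlation. Without Atoh1-CreER tumour 3, 2 genes passed, and the GABAergic (adjusted p = 0.0770) and radial glia calls (adjusted p = 0.0580) ended. Without Atoh1-CreER tumour 1 the radial glia call ended (adjusted p = 0.119) and the microglia list turned (adjusted p = 0.473), which also did not pass without Prom1-CreER tumour 1 or 3 (adjusted p = 0.445 and 0.0804), and the GABAergic call ended without Prom1-CreER tumour 1 or 2 (adjusted p = 0.141 and 0.0732) or with arrays of the same kit (adjusted p = 0.0673). After quantile normalization the GABAergic and microglia calls ended (both adjusted p = 0.0781).

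The Cdkn2c-/- orthotopic tumours were set against the sorted progenitors of the same genotype (6 against 3), the cell that Myc was put into. The MYC target and fibroblast lists were higher in the tumours, and the granule neuron and GABAergic lists were lower. Mgp, a matrix protein, rose by 6.93 ± 0.73, the basement membrane collagen Col4a1 by 6.55 ± 0.47, metallothionein Mt1 by 6.36 ± 0.34 and Ptger3 by 6.32 ± 0.70, above every progenitor sample in 6 of 6 tumours. Mycn rose by 7.76 ± 0.18 at its brightest probe set, while another of its probe sets read 11.41 ± 0.27 (SD, n = 3) in progenitors and 5.62 ± 0.89 (SD, n = 6) in the tumours. Lower were Gad1 (-6.78 ± 0.75), Sfrp1 (-5.93 ± 0.39), Atoh1 (-4.79 ± 0.59) and Cadps2, a regulator of vesicle release (-5.75 ± 1.05). Of 18194 genes 5684 passed, 3020 higher and 2664 lower.

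For ribosome biogenesis, with Pes1 at 1.93 ± 0.14 and Nop16 at 2.38 ± 0.23, 29 of 30 measured members rose, 0 fell and 1 did not pass (30 and 0 adjusted over the list alone), adjusted p = 5.7e-36, and adjusted p = 1.4e-05 with an estimated correlation. Metabolic MYC targets rose, Srm by 3.05 ± 0.21 and the translation repressor Eif4ebp1 by 4.50 ± 0.41. Among its 24 measured members 21 rose, 0 fell and 3 did not pass (22 and 0 adjusted over the list alone), adjusted p = 9.8e-21, and adjusted p = 7.8e-06 with an estimated correlation. Granule neuron genes fell, such as Barhl1 (-4.49 ± 0.29) and Unc5c (-4.43 ± 0.51). In all 0 of 23 measured members rose, 16 fell and 7 did not pass (0 and 17 adjusted over the list alone), adjusted p = 9.5e-11, and adjusted p = 7.1e-04 with an estimated correlation. GABAergic genes shifted down as a list, with Lhx5 (-4.13 ± 0.16) and Tfap2b (-4.21 ± 0.42). There 0 of 21 measured members rose, 8 fell and 13 did not pass (0 and 8 adjusted over the list alone), adjusted p = 2.0e-08, and adjusted p = 4.6e-05 with an estimated correlation. That call ended without dim genes (adjusted p = 0.934). Glycolysis and hypoxia genes rose, Pdk1 by 3.83 ± 0.34 and Aldoa by 2.24 ± 0.27. Over 21 measured members 17 rose, 0 fell and 4 did not pass (18 and 0 adjusted over the list alone), adjusted p = 2.1e-10, and adjusted p = 0.0167 with an estimated correlation. Fibroblast and mural genes rose, Pdgfrb by 5.98 ± 0.56 and Col3a1 by 6.26 ± 0.72, while Pdgfra fell by 2.57 ± 0.70. Of 19 measured members 17 rose, 1 fell and 1 did not pass (17 and 1 adjusted over the list alone), adjusted p = 9.5e-11, and adjusted p = 0.0347 with an estimated correlation. Endothelial genes rose, Emcn by 3.88 ± 0.47 and Pecam1 by 1.92 ± 0.29. Among its 18 measured members 16 rose, 0 fell and 2 did not pass (16 and 0 adjusted over the list alone), adjusted p = 1.3e-08, and adjusted p = 0.208 with an estimated correlation. Microglia genes rose, Lyz2 by 4.91 ± 0.67 and the complement gene C1qa by 4.56 ± 0.76. In all 20 of 22 measured members rose, 0 fell and 2 did not pass (20 and 0 adjusted over the list alone), adjusted p = 9.6e-09, and adjusted p = 0.351 with an estimated correlation. The progenitors were sorted for a fluorescent marker of their lineage and the tumours were not.

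The same orthotopic tumours against the SHH tumours (6 against 16) compare the models of the human Group3 and SHH classes. Sfrp1 (-5.92 ± 0.26), Hsd11b2 (-5.61 ± 0.28), Barhl1 (-5.15 ± 0.19) and Gli1 (-4.96 ± 0.31) fell, below every SHH tumour in 6 of 6 tumours. Ptger3 rose by 6.32 ± 0.47, Tuba4a by 5.60 ± 0.27 and Fkbp11, a protein folding enzyme of the endoplasmic reticulum, by 4.92 ± 0.19. Of 18194 genes 7752 passed, 4614 higher and 3138 lower. Every measured MYC target of ribosome biogenesis rose, Nop16 by 2.34 ± 0.16 and Pes1 by 1.41 ± 0.09. There 30 of 30 measured members rose, 0 fell and 0 did not pass (30 and 0 adjusted over the list alone), adjusted p = 3.2e-26, and adjusted p = 8.5e-04 with an estimated correlation. Metabolic MYC targets rose, Ppat by 1.23 ± 0.09 and Ldha by 2.08 ± 0.17. Over 24 measured members 21 rose, 0 fell and 3 did not pass (21 and 0 adjusted over the list alone), adjusted p = 7.0e-12, and adjusted p = 0.00155 with an estimated correlation. Granule neuron genes shifted down as a list, with Atoh1 (-5.53 ± 0.40) and Zic1 (-1.44 ± 0.12). Of 23 measured members 0 rose, 10 fell and 13 did not pass (0 and 10 adjusted over the list alone), adjusted p = 6.8e-08, and adjusted p = 0.00909 with an estimated correlation.

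Hypoxia and glycolysis genes rose in the orthotopic tumours, Pdk1 by 4.13 ± 0.23 and Pgk1 by 1.48 ± 0.14. Among its 21 measured members 16 rose, 0 fell and 5 did not pass (17 and 1 adjusted over the list alone), adjusted p = 6.8e-08, and adjusted p = 0.0692 with an estimated correlation. Radial glia genes fell, such as Sox9 (-3.92 ± 0.29) and Id2 (-1.88 ± 0.33), while Cd44 rose by 1.83 ± 0.45. In all 4 of 22 measured members rose, 11 fell and 7 did not pass (4 and 11 adjusted over the list alone), adjusted p = 0.0356, and adjusted p = 0.712 with an estimated correlation. Endothelial genes rose, Egfl7 by 2.24 ± 0.19, while Sox18 fell by 2.94 ± 0.34. There 15 of 18 measured members rose, 1 fell and 2 did not pass (15 and 1 adjusted over the list alone), adjusted p = 0.00148, and adjusted p = 0.762 with an estimated correlation. Fibroblast genes rose, Mgp by 5.00 ± 0.50 and Col1a2 by 3.25 ± 0.43. Over 19 measured members 17 rose, 1 fell and 1 did not pass (17 and 1 adjusted over the list alone), adjusted p = 1.1e-05, and adjusted p = 0.327 with an estimated correlation. The radial glia call ended in a fit of only these groups (adjusted p = 0.0563), after quantile normalization (adjusted p = 0.0764) and without dim genes (adjusted p = 0.132), as did the endothelial call without dim genes (adjusted p = 0.132).

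Between the 2 SHH models (8 against 8), Nestin-Cre tumours were higher than Ptch1+/- tumours in the endothelial and interferon lists at the preset correlation. Of the Ptch1+/- tumours 2 read high at Cdkn2c. Mdk, the growth factor midkine, rose by 4.03 ± 0.64, Cldn5, the tight junction protein of brain endothelium, by 2.75 ± 0.41 and Ifit1, an interferon target, by 2.94 ± 0.76. Ptch1 (-4.72 ± 0.73), Fgfr4 (-2.83 ± 0.42) and the muscle transcription factor Myod1 (-3.07 ± 0.31) fell, below every Ptch1+/- tumour in 6 of 8, 6 of 8 and 8 of 8 Nestin-Cre tumours. In all 3275 of 18194 genes passed, 1999 higher and 1276 lower, and after quantile normalization 1610 were higher and 1576 lower. Endothelial genes rose, Esam by 1.40 ± 0.22. Of 18 measured members 17 rose, 0 fell and 1 did not pass (17 and 0 adjusted over the list alone), adjusted p = 6.2e-13, and adjusted p = 0.341 with an estimated correlation. Interferon genes shifted up as a list, with Ifi27 at 2.62 ± 0.45 and H2-Aa at -1.28 (adjusted p = 0.00405 in a fit of only these groups). Among its 24 measured members 7 rose, 1 fell and 16 did not pass (10 and 1 adjusted over the list alone), adjusted p = 0.0133, and adjusted p = 0.846 with an estimated correlation.

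Cell cycle genes shifted down in Nestin-Cre tumours as a list, with Mcm7 (-0.49 ± 0.09) and Aurkb (-0.91 ± 0.18). In all 0 of 29 measured members rose, 9 fell and 20 did not pass (0 and 11 adjusted over the list alone), adjusted p = 2.7e-04, and adjusted p = 0.691 with an estimated correlation. Fibroblast and mural genes shifted up, with Rgs5 at 2.60 ± 0.47. There 5 of 19 measured members rose, 0 fell and 14 did not pass (5 and 0 adjusted over the list alone), adjusted p = 0.0226, and adjusted p = 0.782 with an estimated correlation. Glycolysis genes shifted up, with the glucose transporter gene Slc2a1 at 1.49 ± 0.27. Over 21 measured members 6 rose, 0 fell and 15 did not pass (6 and 0 adjusted over the list alone), adjusted p = 0.0363, and adjusted p = 0.782 with an estimated correlation. Metabolic MYC targets shifted up, with Hspe1 at 0.54 ± 0.10 and Srm at 0.77 ± 0.15. Of 24 measured members 6 rose, 0 fell and 18 did not pass (9 and 0 adjusted over the list alone), adjusted p = 0.0363, and adjusted p = 0.709 with an estimated correlation. Microglia genes shifted down as a list, and of them Lyz2 passed (-1.34 ± 0.47, adjusted p = 0.0727 with arrays of the same kit). Among its 22 measured members 0 rose, 1 fell and 21 did not pass (0 and 0 adjusted over the list alone), adjusted p = 0.0363, and adjusted p = 0.906 with an estimated correlation. With arrays of the same kit alone the MYC metabolism, microglia and fibroblast calls ended (adjusted p from 0.0665 to 0.0819), and in a fit of only these groups the MYC metabolism call (adjusted p = 0.146). Without dim genes the MYC metabolism, microglia, glycolysis and interferon calls ended (adjusted p from 0.0692 to 0.0952), and after quantile normalization the microglia call (adjusted p = 0.0631).

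SHH against WNT tumours (16 against 3) sets tumours higher in the granule neuron list beside tumours higher in WNT targets, the latter at the preset correlation alone. Slc17a6, a vesicular glutamate transporter, rose by 6.91 ± 0.69, Atoh1 by 6.17 ± 0.52 and Nhlh2 by 6.12 ± 0.31, above every WNT tumour in 16 of 16 SHH tumours. Lower were the protease inhibitor gene A2m (-7.42 ± 0.71), Aldh1a1, which makes retinoic acid (-6.10 ± 0.64), and Id3 (-5.72 ± 0.54). Of 18194 genes 7561 passed, 3506 higher and 4055 lower. WNT targets fell, such as Dkk1 (-2.84 ± 0.33) and Notum (-4.02 ± 0.49, below every WNT tumour in 11 of 16). Without WNT tumour 2 these were at -3.97 and -6.00 and the list at adjusted p = 1.21e-27. In all 0 of 19 measured members rose, 17 fell and 2 did not pass (0 and 17 adjusted over the list alone), adjusted p = 1.7e-09, and adjusted p = 0.0606 with an estimated correlation. Granule neuron genes rose, Barhl1 by 5.44 ± 0.26 and Zic1 by 3.15 ± 0.16, while Gabra6 fell by 3.99 ± 0.87. There 17 of 23 measured members rose, 3 fell and 3 did not pass (17 and 4 adjusted over the list alone), adjusted p = 2.3e-15, and adjusted p = 6.9e-05 with an estimated correlation. Cell cycle genes rose, Mcm6 by 2.13 ± 0.13 and Pcna by 1.45 ± 0.12. Over 29 measured members 28 rose, 0 fell and 1 did not pass (28 and 0 adjusted over the list alone), adjusted p = 1.8e-19, and adjusted p = 0.012 with an estimated correlation. Ribosome biogenesis targets rose, Nop56 by 1.99 ± 0.13. Of 30 measured members 19 rose, 0 fell and 11 did not pass (20 and 0 adjusted over the list alone), adjusted p = 2.7e-09, and adjusted p = 0.0903 with an estimated correlation.

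Metabolic MYC targets rose in SHH tumours, Shmt2 by 2.15 ± 0.26, while Ldha fell by 1.23 ± 0.23. Among its 24 measured members 18 rose, 1 fell and 5 did not pass (18 and 1 adjusted over the list alone), adjusted p = 1.1e-06, and adjusted p = 0.0495 with an estimated correlation. Choroid plexus genes fell, such as Msx1 (-3.57 ± 0.34) and Kcnj13 (-4.28 ± 0.56). In all 2 of 28 measured members rose, 14 fell and 12 did not pass (2 and 14 adjusted over the list alone), adjusted p = 0.0012, and adjusted p = 0.548 with an estimated correlation. Fibroblast genes fell, such as Dcn (-6.04 ± 0.74) and Postn (-4.69 ± 0.61). There 0 of 19 measured members rose, 13 fell and 6 did not pass (0 and 14 adjusted over the list alone), adjusted p = 5.5e-04, and adjusted p = 0.491 with an estimated correlation. Astrocyte genes fell, such as Fgfr3 (-3.06 ± 0.29) and Clu (-3.92 ± 0.58). Over 14 measured members 0 rose, 10 fell and 4 did not pass (1 and 11 adjusted over the list alone), adjusted p = 0.00263, and adjusted p = 0.548 with an estimated correlation. Interferon genes shifted down as a list, with Ifit3 (-3.01 ± 0.71). Of 24 measured members 0 rose, 10 fell and 14 did not pass (0 and 11 adjusted over the list alone), adjusted p = 0.0352, and adjusted p = 0.976 with an estimated correlation. Without WNT tumour 2 the interferon (adjusted p = 0.865) and astrocyte calls (adjusted p = 0.0577) ended, and without dim genes the choroid plexus call (adjusted p = 0.168).

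The carcinomas were compared on the second array type with the repeat of Blbp-Cre tumour 1 (4 against 1), the only medulloblastoma there. By their genotype labels 3 carcinomas came from Gad2-IRES-Cre and 1 from Blbp-Cre mice, so tumour type is largely confounded with Cre line. The repeat's labels conflict, so these labels may hold errors and the extent of the confounding is uncertain. Against this 1 tumour the carcinomas were higher in the choroid plexus list, at the preset correlation alone, and lower in the hindbrain list, which does not show how carcinomas differ from medulloblastomas in general. Cldn1, a tight junction protein, rose by 5.15 ± 0.42, adjusted p = 0.029, Otx2, a transcription factor of choroid plexus and forebrain, by 4.26 ± 0.38, adjusted p = 0.031 and Kcne2 by 3.78 ± 0.34, adjusted p = 0.0314, higher in 4 of 4 carcinomas. Lower were Crabp1 (-5.92 ± 0.21, adjusted p = 0.0137), Olig3 (-4.84 ± 0.25, adjusted p = 0.0172), Hoxa5 (-4.06 ± 0.23, adjusted p = 0.0196) and Hoxa9 (-4.01 ± 0.08, adjusted p = 0.0081), lower in 4 of 4. The shared tumour was itself high among in situ tumours on the first array type: Hoxa9 was at 8.91 in it, 9.09 in Gad2-IRES-Cre tumour 4 and 8.38 in Ptf1a-Cre tumour 1, and between 4.90 and 5.81 in the other 9. For choroid plexus epithelium, with Ttr at 1.61 ± 0.20, 4 of 26 measured members rose, 0 fell and 22 did not pass (14 and 0 adjusted over the list alone), adjusted p = 2.6e-10, and adjusted p = 0.369 with an estimated correlation. Midbrain and hindbrain genes shifted down as a list, with Hoxb3 (-2.27 ± 0.09) and Hoxd3 (-1.78 ± 0.09). Among its 15 measured members 0 rose, 3 fell and 12 did not pass (0 and 7 adjusted over the list alone), adjusted p = 2.4e-10, and adjusted p = 2.8e-06 with an estimated correlation. Ribosome biogenesis targets shifted down, with Rrp12 (-0.89 ± 0.08) and Bop1 (-0.79 ± 0.09). In all 0 of 28 measured members rose, 2 fell and 26 did not pass (0 and 2 adjusted over the list alone), adjusted p = 0.00128, and adjusted p = 0.876 with an estimated correlation. Metabolic MYC targets shifted down, and of them Odc1 passed (-0.83 ± 0.11). There 0 of 24 measured members rose, 1 fell and 23 did not pass (0 and 3 adjusted over the list alone), adjusted p = 0.0106, and adjusted p = 0.794 with an estimated correlation.

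Cell cycle genes also shifted down in the carcinomas as a list, and of them E2f1 passed (-1.05 ± 0.07). Over 28 measured members 0 rose, 1 fell and 27 did not pass (0 and 1 adjusted over the list alone), adjusted p = 0.015, and adjusted p = 0.876 with an estimated correlation. Astrocyte genes shifted up, with Ndrg2 at 1.11 and Clu at 1.72. Of 14 measured members 0 rose, 0 fell and 14 did not pass (3 and 0 adjusted over the list alone), adjusted p = 0.0463, and adjusted p = 0.732 with an estimated correlation. In limma 637 of 21448 genes passed, 328 higher and 309 lower, and 4937 had an unadjusted p under 0.05. With carcinoma 1, 2, 3 or 4 left out 0 genes passed (3976 to 4575 at an unadjusted p under 0.05), with a trend and robust spread 330 passed, and among the 13455 genes with 4 different carcinoma values 109 passed, without Ttr, Bop1 and Odc1 (adjusted p = 0.0613, 0.0859 and 0.0864). The astrocyte call ended without carcinoma 1 or 4 (adjusted p = 0.0524 and 0.0924) and without dim genes (adjusted p = 0.106).

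Differences from the tumour run on both array types place the carcinomas beside the other groups, without a test since the tables were normalized apart. Over 26 choroid plexus genes the mean of each tumour's median difference was 2.60 ± 0.78 (SD, n = 4) in carcinomas, 0.95 ± 1.31 (SD, n = 4) in the other Blbp-Cre tumours, 0.11 ± 1.30 (SD, n = 3) in Ptf1a-Cre, -0.57 ± 0.31 (SD, n = 4) in Gad2-IRES-Cre and 0.26 ± 0.24 (SD, n = 3) in WNT tumours.

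Among the 26 fixed lists, 8 passed in none of the 12 comparisons. They were motile cilia, the photoreceptor programme, p53 targets, erythroid cells, human Group3 markers, the oligodendrocyte lineage and embryonic and forebrain genes (smallest adjusted p from 0.0565 to 0.158).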

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

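The splits of the tumours were planned before the data were examined, and the tests on Mycn, on T and NK cell genes and on choroid plexus genes were chosen after the results were seen.

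A sample lay far from the others of its group in 10 of 88 groups of values for the genes the models were built on, where chance flags about 1 in 20 groups (4.4). In Gad2-IRES-Cre tumour 4 Atoh1 was at 7.70 (others 4.14 to 4.66) and Ptf1a at 5.61 (3.42 to 3.59). Among the Ptch1+/- SHH tumours, Prom1 was at 10.68 in replicate 2 (8.08 to 9.28) and Nes at 9.13 in replicate 6 (7.10 to 7.97). Cdkn2c was at 5.85 in Atoh1-CreER tumour 2 (6.66 to 6.79) and Prom1 at 9.82 in Prom1-CreER tumour 2 (8.97 to 9.11). In the carcinomas Cdkn2c was at 8.91 in replicate 3 (7.36 to 7.56), Fabp7 at 10.81 in replicate 1 (9.19 to 9.29), and in replicate 2 Ptch1 was at 9.53 (9.90 to 9.94) and Prom1 at 6.56 (7.66 to 7.88). The Cdkn2c readings of 9.13 and 9.10 in Ptch1+/- SHH tumours were not flagged, since each has the other as its neighbour.

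Signal was also read at probe sets without a single gene in the annotation, which no comparison used. Of 10143 such probe sets, 14 were above every progenitor sample by over 2 log2 in every orthotopic tumour, of all 3 donor groups. Among these the 3 largest differences, from the mean of the orthotopic groups to the progenitors, were 5.60, 4.80 and 4.18.

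The brightest Mycn probe set was high in each orthotopic tumour. Over the other 2 Mycn probe sets the orthotopic tumours differed from the in situ tumours by 0.15 log2, which argues against a transcript that all 3 measure. Among Affyexpress arrays alone the difference was 7.40, which argues against the labelling kit. The lowest orthotopic array lay 6.11 log2 above the highest other array, the only gap above 3 log2 among 45101 probe sets, so a sequence carried by the construct of the orthotopic tumours may be what this probe set reads. The construct's sequence is not given, and no biological explanation was tested.

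T and NK cell genes were higher in situ than orthotopic, by a median of 0.74 log2 (SE over 19 members 0.34). Endothelial and fibroblast genes moved by -0.41 (SE over 37 members 0.065), but both calls ended with an estimated correlation and sites differ, so tumour cell share is open. An SE over members is taken over genes and does not measure the spread over tumours. The labelling kit is excluded as the whole cause, since the list passed among Affyexpress arrays alone (adjusted p = 1.97e-14). The orthotopic hosts were immunocompromised, which may lower these genes, but spontaneous SHH tumours lay above the orthotopic tumours by only 0.10 (SE 0.025), so the host cannot be told apart from the site and origin of the tumours. The bound for that test was set after its value had been seen.

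Ttr was above 10 in 5 in situ tumours, but also in some orthotopic, SHH and WNT tumours. The highest Ttr outside the Blbp-Cre line lay 9.55 log2 above that line's lowest, but Ttr defined the 5, so this tests no cause. Of the other choroid plexus genes, 77.8% correlated with Ttr above 0.5 across the 12 tumours, against a 95th percentile of 22.2% in random lists of like level. Choroid plexus cells, or their programme in tumour cells, may be the source, which these data do not separate.

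Other splits of the same tumours were counted with the real one. Of 100 splits, 1 gave as many genes for in situ against SHH (8003, highest other 52), against WNT (7753, highest other 3954) and against orthotopic (1858, highest other 43), for orthotopic against SHH (7752, highest other 2274), for Nestin-Cre against Ptch1+/- SHH (3275, highest other 914) and for SHH against WNT (7561, highest other 4333), and of 84 splits 1 for orthotopic against progenitors (5684, highest other 1882). Chance can be excluded for these. Chance cannot be excluded for Blbp-Cre against Gad2-IRES-Cre (9 of 100 splits, 217, highest other 520), Blbp-Cre against Ptf1a-Cre (4 of 56 splits, 138, highest other 589) or Gad2-IRES-Cre against Ptf1a-Cre (7 of 35 splits, 32, highest other 763). For Atoh1-CreER against Prom1-CreER the real count of 0 by limma (725 at an unadjusted p under 0.05) makes 35 of 35 splits give as many whatever the grouping, so this says nothing about chance (highest other 16). Splits of the Ptf1a-Cre with the Blbp-Cre or Gad2-IRES-Cre tumours that call several times the real count point to a structure of those tumours, which was not tested.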

How the results depend on the processing

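The settings without tumours of high Ttr, with 4 different carcinoma values and on Mycn were chosen after seeing the data, and all others before. No paired analysis was possible because no tumour or animal is in both sides of a comparison. Signal over background limits dim genes, the error of the kit shift limits comparisons across kits, and 3 to 5 tumours limit those between Cre lines. Of the gene values named, tested again under each setting that applied, 3786 kept direction and side of the threshold, 166 no longer passed, 16 newly passed and 8 reversed, and of the list values 1417, 143, 0 and 13 did. Unless said otherwise the cause was not tested.

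With arrays of 1 kit 48 genes passed between Blbp-Cre and Gad2-IRES-Cre (217 as reported), 0 between Blbp-Cre and Ptf1a-Cre (138, by limma with 2054 at an unadjusted p under 0.05) and 1 between Gad2-IRES-Cre and Ptf1a-Cre (32), and 4 lists between the SHH models (7). With only the groups compared the Cre line counts were 0, 8 and 0 (1458, 1909 and 907 at an unadjusted p under 0.05 by limma), with 2 lists between Gad2-IRES-Cre and Ptf1a-Cre (1) and 7 between Atoh1-CreER and Prom1-CreER (4). Both settings have fewer arrays to estimate the spread. Quantile normalization left 2 lists between Atoh1-CreER and Prom1-CreER.

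Without dim genes 1200 genes passed for in situ against orthotopic (1858), 84, 32 and 14 between the Cre lines in the order above, and 2 lists between Blbp-Cre and Ptf1a-Cre (6), 0 between Gad2-IRES-Cre and Ptf1a-Cre and 3 between the SHH models. The GABAergic list then reversed for in situ against orthotopic (adjusted p = 0.685). Fewer genes are tested there. A trend with robust spread gave 330 genes for the carcinomas (637), and genes with 4 different carcinoma values gave 109, with 10 lists (6). With all genes the mean correlation with the Myc model was 0.55 (0.64), still the highest in 12 of 12 tumours.

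With an estimated correlation the lists that passed were 5 for in situ against SHH (10), 3 against WNT (9), 2 against orthotopic (11), 2, 1 and 0 between the Cre lines (4, 6 and 1), 0 between Atoh1-CreER and Prom1-CreER, 3 for orthotopic against SHH (7), 0 between the SHH models, 3 for SHH against WNT (9) and 1 for the carcinomas.

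Without the 5 tumours with Ttr above 10, 825 genes passed for in situ against orthotopic and 34, 54 and 54 between the Cre lines, with 2 lists between Blbp-Cre and Ptf1a-Cre and 4 between Gad2-IRES-Cre and Ptf1a-Cre. Between Blbp-Cre and either other line this leaves 1 Blbp-Cre tumour, which tests neither line. Since Ttr is itself a choroid plexus gene, the choice fixes the change of that list. The choroid plexus list reversed in all 6 in situ comparisons but that with WNT, against SHH (adjusted p = 0.941) and orthotopic (adjusted p = 0.0352) and between the Cre lines (adjusted p = 0.769, 0.976 and 0.578). Reversed too were microglia between Blbp-Cre and Gad2-IRES-Cre (adjusted p = 0.649), and between Blbp-Cre and Ptf1a-Cre the cell cycle, microglia, T and NK cell and interferon lists (adjusted p = 0.781, 0.189, 0.776 and 0.0981). Among genes Cldn1 (-0.14), Kcne2 (-0.25) and Tap2 (-0.01) reversed between Blbp-Cre and Gad2-IRES-Cre, and Aif1 (-0.08), Cd74 (-1.15) and Kcne2 (-0.20) between Blbp-Cre and Ptf1a-Cre. Mycn in orthotopic tumours against progenitors was -0.18 with the mean of its probe sets and -5.79 with another.

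With a single array left out, gene counts ran from 0 to 2 between Atoh1-CreER and Prom1-CreER, 51 to 406, 70 to 244 and 16 to 70 between the Cre lines, and 0 to 0 for the carcinomas (3976 to 4575 at an unadjusted p under 0.05 by limma). Lists ran from 2 to 8 between Atoh1-CreER and Prom1-CreER, 4 to 7, 3 to 6 and 1 to 6 between the Cre lines and 6 to 9 for the carcinomas. Without Atoh1-CreER tumour 1 the microglia list of Atoh1-CreER against Prom1-CreER reversed (adjusted p = 7.49e-05 to 0.473 over single arrays), and without Ptf1a-Cre tumour 1 the choroid plexus list between Gad2-IRES-Cre and Ptf1a-Cre (adjusted p = 4.42e-09 to 0.719).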

Other observations

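The readings in this part were chosen after the values were seen, and no cause was tested.

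Hox genes, which set position along the hindbrain and spinal cord, divided the in situ tumours across the Cre lines. Hoxa5 lay between 8.66 and 9.35 in 3 tumours, 1 of each Cre line (Blbp-Cre 1, Gad2-IRES-Cre 4 and Ptf1a-Cre 1), and between 5.0 and 6.6 in the other 9. In the carcinomas, on the second array type, Hoxa5 was between 4.85 and 5.42 and Hoxa9 between 5.75 and 5.84, against 9.23 and 9.82 in the repeat of Blbp-Cre tumour 1. The lower Hox genes of the carcinomas are thus read against a tumour with high Hox genes.

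WNT tumour 2 was unlike the other WNT tumours. The mean level of the WNT target list, relative to all arrays, was 0.35 log2 there and 3.35 and 4.40 in the others, with Lef1 at 5.43 against 9.48 and 9.51 and Ttr at 13.44 against 4.65 and 6.88. Sorted progenitors carried GABAergic transcripts, with Gad1 at 9.68 ± 0.25 (SD, n = 3), against 2.91 ± 0.10 (SD, n = 6) in the orthotopic tumours of the same genotype.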
